A study of Homo sapiens with 14 samples.

How the data were processed

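Total RNA from 14 cultures of LNCaP cells, an androgen-responsive human prostate cancer cell line, had been biotin-labelled and hybridised to Affymetrix HG-U133 Plus 2.0 arrays, 1 culture per array. Per the labels, the cultures fell into 5 groups: 2 controls without dihydrotestosterone (DHT), 3 DHT controls, and 3 cultures each with bicalutamide, polyamide 1 and polyamide 2. The labels call the arrays of a group biological replicates. The treatment text gives 10 µM of each compound, polyamides from 48 h and bicalutamide from 2 h before 1 nM DHT, and 16 h with DHT in medium with charcoal-stripped serum. Sample descriptions call the treated cells not stimulated with DHT, whereas the series design and the treatment text say that they were. Groups were taken from the sample names, treated cells are described as DHT-stimulated after the design text, and the androgen lists were also set against the cultures without DHT for this reason.

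The deposited values were 1 intensity per probe set and array on a linear scale, all above 0, from 0.0185 to 13457. The summary algorithm and any scaling by the authors are not given in the sources used here. Mean intensity per array ran from 108 to 197 and median intensity from 10.1 to 18.3, so the arrays had not been brought to a common level. Of 54675 probe sets, 62 were Affymetrix controls and were left out of all tests. Of the other 54613, 41091 carried 1 gene symbol and were used, 1801 carried several and 11721 were not listed with a name in the probe table. No column of the table was left unused.

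Intensities were analysed as log2(intensity + 20) and quantile normalised. Probe sets with a mean above the 30th percentile of all probe sets were kept, and each gene was represented by its probe set with the highest mean over all 14 arrays, which gave 15913 genes. One linear model with the 5 groups was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, and p was adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05. Log2 changes are given with their standard error (SE) and tests are two-sided. The median residual SD was 0.164 with 9 residual and 4.39 prior degrees of freedom. The number of arrays limits the precision of every value, most of all in the comparison with the 2 unstimulated arrays. Figures were drawn with Python 3.11.15.

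The rule fixed for normalisation was to keep the values as deposited unless the medians of the log2 columns spanned over 0.5. The medians of log2(intensity + 20) spanned 0.346, under that limit, and the medians of log2(intensity) spanned 0.851. Mean intensities differed 1.82-fold between arrays. Quantile normalisation was therefore used, a departure from the letter of the rule that was decided after the levels of the arrays had been seen and before any test was run. Counts from the values as deposited and from median-centred columns stand beside the counts of the 5 planned comparisons, of bicalutamide against unstimulated arrays and of unnamed probe sets.

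The planned comparisons and tests, the fixed gene lists and the rule for named genes were chosen before the data were examined. Other tests were added after results had been seen. Among them were the list of NRF2 target genes, the gene span correlations and the division of DHT controls between changes. Named genes were, in each comparison, the 10 with the largest increase and the 10 with the largest decrease among called genes whose 2 groups of arrays did not overlap, 6 fixed genes, and up to 4 called members of each list with the largest change. Of the 6 fixed genes, KLK3, KLK2, FKBP5 and TMPRSS2 were tested and the other 2 were not analysed here. For every gene taken by that rule, the arrays of the 2 groups compared did not overlap. A few list members outside the rule are named where they moved against their list and were chosen after their values were seen.

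The 21 lists held 328 genes, of which 269 were tested. They covered genes induced and repressed by androgen, synthesis of cholesterol, fatty acids and polyamines, hypoxia and glycolysis, the unfolded protein response, the cell cycle, p53 targets, NF-kB targets, the interferon response, heat shock, immediate early genes, histones, ribosome biogenesis and ribosomal proteins. A further 5 lists held luminal, basal, neuroendocrine, stromal, and immune and endothelial markers. Lists were tested against all other genes with camera in limma, with a preset correlation between genes of 0.01, and adjusted over the 21 lists within a comparison. An estimated correlation and the fry test were run as alternatives. List counts are given over all genes tested and adjusted over the list alone.

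DHT-induced genes were those called and at least 2-fold higher in DHT controls than without DHT. For each treatment, the number lowered and the median share of the DHT change reversed were computed. Beside them stand values from 100 simulations in which an unchanged group shared its controls with the DHT comparison. DHT-induced genes were selected anew in each simulation. Shares carry 95% Wilson intervals, which treat the genes as independent and hold no variation between arrays. Correlations of log2 changes were taken across genes, which are not independent replicates.

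The model fit and calls were tested on simulated data with 200 changed genes among the 15913. Independent noise with each gene's SD was added to the gene means after normalisation. Normalisation, the choice of probe sets and correlation between genes were therefore not tested. At the group sizes of polyamide 1 against DHT controls the fit recovered 62.7% of 1.5-fold, 95.5% of 2-fold and 100% of 3-fold changes, with 5 false calls among 177. At the sizes of DHT controls against unstimulated arrays these were 49.3%, 94% and 100%, with 6 false calls among 168. Alternatives were other scalings, pseudocounts of 1 and 100, other filters on dim probe sets, other ways to choose a probe set per gene, omission of probe sets with _x_at or _s_at names, variance priors with trend, array weights, a fit of the 2 compared groups alone, a fold limit, a replicate block and omission of each array. Their effects are given in the closing section. A list of NRF2 target genes and gene spans from RefSeq annotation of GRCh38.p14 were used only there.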

Results

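Expression was measured on 14 arrays of LNCaP cells, an androgen-responsive human prostate cancer line. Cells without dihydrotestosterone (DHT), the potent androgen made from testosterone, were on 2 arrays, and 3 arrays each held DHT controls and cells with DHT plus bicalutamide, polyamide 1 or polyamide 2. Bicalutamide is an antiandrogen drug, and pyrrole-imidazole polyamides are synthetic ligands that bind the minor groove of DNA. The treatment text names a polyamide targeted to the androgen response element and a control polyamide, and the labels do not say which of them carries which number. From general knowledge of the published study, polyamide 1 is taken to be the targeted compound and polyamide 2 the control. This assignment could not be checked in the sources used here.

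Mean intensity per array ran from 108 to 197. Correlations between arrays were 0.985 to 0.991 within groups and 0.967 to 0.991 between groups. The 3' to 5' signal ratio of ACTB, a sign of RNA quality, was 2.23 ± 0.0332 (SD, n = 2) without DHT and 2.44 ± 0.465 (SD, n = 3) in DHT controls. It was 2.62 ± 0.543 with bicalutamide, 2.30 ± 0.557 with polyamide 1 and 1.96 ± 0.302 with polyamide 2 (SD, n = 3 each). The GAPDH ratio had group means from 1.05 to 1.15. The first principal component, with 38.3% of the variance, set the unstimulated and bicalutamide arrays apart from the other 3 groups.

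**Figure D1:**
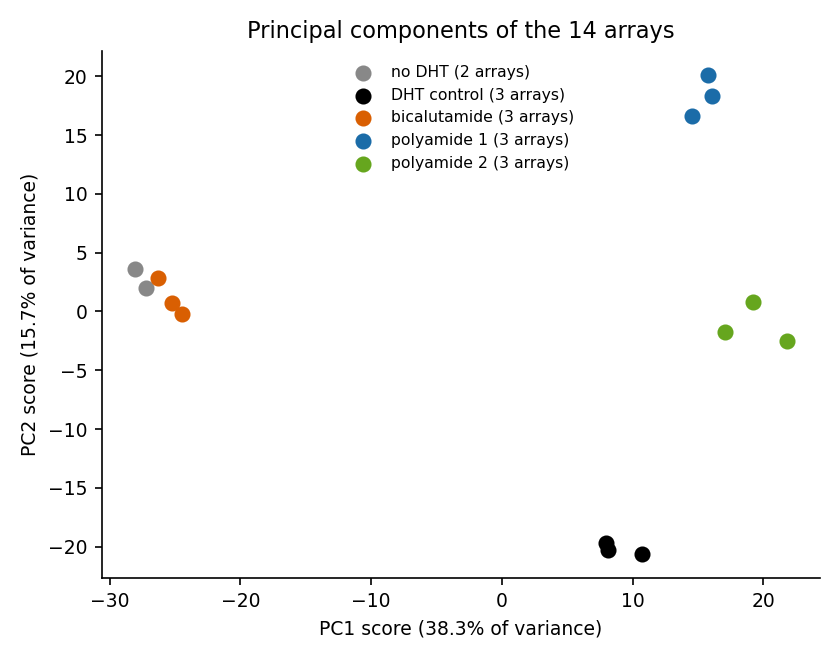
Principal components 1 (38.3% of variance) and 2 (15.7%) of the 14 arrays, 1 point per array, coloured by group. The unstimulated and bicalutamide arrays lay together at -28.1 to -24.4 on component 1, and DHT controls, polyamide 1 and polyamide 2 lay apart from each other on component 2.

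The first comparison asked which genes respond to DHT, with 3 DHT controls against 2 unstimulated arrays. FKBP5, a co-chaperone of steroid receptors and a standard androgen target, rose by 3.74 ± 0.09 on the log2 scale (SE, adjusted p = 2.04e-11). STEAP4, a metalloreductase, had the largest rise at 4.4 ± 0.12, which is 21-fold. KLK3, which encodes prostate-specific antigen, rose by 2.19 ± 0.12 from 8.91 ± 0.26 (SD, n = 2) to 11.10 ± 0.07 (SD, n = 3), and its neighbour KLK2 by 3.53 ± 0.15. TMPRSS2, a membrane serine protease, rose by 2.51 ± 0.09. Other large rises were those of the transcription factor MAF at 3.59 ± 0.15, the stress-response gene NDRG1 at 3.26 ± 0.17, the condensin subunit NCAPD3 at 3.21 ± 0.10, EAF2 at 2.84 ± 0.15, CCDC141 at 2.84 ± 0.16 and MICAL1 at 2.82 ± 0.13. The largest falls were those of LRRN1 at -2.99 ± 0.14 (7.96-fold lower), the kappa opioid receptor OPRK1 at -2.98 ± 0.11, the ubiquitin ligase MID1 at -2.61 ± 0.15, the kinase inhibitor CAMK2N1 at -2.60 ± 0.12, AMIGO2 at -2.42 ± 0.16, the glycosidase gene MANEA at -2.31 ± 0.11 and UGT2B15, which glucuronidates androgens, at -2.25 ± 0.15. For KLK2, when probe sets with _x_at or _s_at names were left out, a dimmer probe set took its place and gave -0.12.

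Of 31 tested genes known to be induced by androgen, 27 rose and 1 fell, or 27 and 2 adjusted over the list alone (median 2.12, camera adjusted p = 4.53e-41). The member that fell was ACP3, prostatic acid phosphatase, at -1.10. Of 12 genes known to be repressed by androgen, 8 fell and 0 rose, or 8 and 1 adjusted over the list alone (median -1.95, adjusted p = 1.01e-11). The genes that fell included the dopamine-synthesis enzyme DDC at -2.10 ± 0.15.

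In the cholesterol list 10 of 18 genes rose with DHT and 1 fell, or 11 and 2 adjusted over the list alone (median 0.43, adjusted p = 1.09e-06). They included HMGCS1 at 1.09 ± 0.14, IDI1 at 1.05 ± 0.10, SQLE at 0.85 ± 0.11 and INSIG1, a regulator that holds back the pathway, at 1.09 ± 0.12. The member that fell was the sterol reductase TM7SF2 at -0.50, and IDI1 gave -0.10 on the probe set used when _x_at and _s_at probe sets were left out. In the fatty acid list 5 of 10 rose and 0 fell, or 6 and 1 adjusted over the list alone, among them FASN at 0.93 ± 0.21, ACACA at 0.85 ± 0.12 and the elongase ELOVL5 at 0.70 ± 0.09. That list had an adjusted p = 0.00105, and adjusted p = 0.0795 with an estimated correlation. Of 8 polyamine genes, 3 rose and 0 fell, or 5 and 0 adjusted over the list alone (adjusted p = 0.000171). These were the spermine synthase gene SMS at 1.40 ± 0.11, the ornithine decarboxylase gene ODC1 at 1.12 ± 0.10 and SAT1, which degrades polyamines, at 1.02 ± 0.15.

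Among 18 hypoxia and glycolysis genes 4 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.26, adjusted p = 0.00113, and adjusted p = 0.17 with an estimated correlation). The hypoxia-inducible ANKRD37 rose by 1.76 ± 0.10, the glucose transporter SLC2A3 by 1.38 ± 0.17 and hexokinase HK2 by 1.32 ± 0.13, while the peptide hormone gene ADM was at -0.67. Of 21 genes of the unfolded protein response 6 rose and 0 fell, or 8 and 0 adjusted over the list alone (adjusted p = 0.000108). Called members included the chaperone genes DNAJB9 at 1.34 ± 0.10, CRELD2 at 0.80 ± 0.11 and CALR at 0.67 ± 0.17. Of 33 cell cycle genes 8 fell and 0 rose, or 12 and 0 adjusted over the list alone (median -0.21, adjusted p = 9.68e-05, and adjusted p = 0.17 with an estimated correlation). They included cyclin E2 (CCNE2) at -0.98 ± 0.15 and the replication helicase subunits MCM2 at -0.60 ± 0.14 and MCM3 at -0.56 ± 0.13.

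Luminal epithelial markers had 3 of 8 higher and 1 lower, or 4 and 1 adjusted over the list alone (median 0.47, adjusted p = 0.0159, and adjusted p = 0.0727 with an estimated correlation). The keratins KRT8 and KRT18 rose by 1.63 ± 0.09 and 1.06 ± 0.09, GRHL2 rose by 0.95 ± 0.10, and EPCAM changed by -0.37 ± 0.09. Camera made no call for the other lists. Of 21 p53 target genes 2 were higher and 4 lower, or 3 and 7 adjusted over the list alone (adjusted p = 0.0894, but 0.0354 without DHT control 3 and 0.0497 without a filter, both lower). Among them were the death receptor gene TNFRSF10B at 1.11 ± 0.09 and SESN1 at -1.19 ± 0.11. Of 9 immediate early genes 3 were higher and 3 lower by either adjustment (adjusted p = 0.569). The called genes included KLF4 at 1.61 ± 0.11 and JUN at -0.81 ± 0.14. Of 9 NF-kB targets 2 were higher and 0 lower by either adjustment, namely NFKBIA at 1.04 ± 0.14 and TNFAIP3 at 0.62 ± 0.17, both of which restrain NF-kB (adjusted p = 0.341; median -0.04, mean 0.16). Of 15 interferon genes 0 were higher and 2 lower, or 1 and 3 adjusted over the list alone (adjusted p = 0.183, but 0.0497 without a filter). Of 8 heat shock genes HSPB1 alone was lower, at -0.43 ± 0.09 (adjusted p = 0.868). Of 8 histone genes only H2BC21 was called, at 0.75 ± 0.12 (adjusted p = 0.861). No member was called among 12 ribosome biogenesis genes (adjusted p = 0.825; median -0.01, mean 0.04) or 10 ribosomal protein genes (adjusted p = 0.833).

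Markers of other cell types gave no call as lists. Of 8 stromal markers 1 was higher and 2 lower, or 2 and 2 adjusted over the list alone (adjusted p = 0.569, but 0.0436, called lower, without DHT control 3). Examples were COL3A1 at -0.95 ± 0.16 and FN1 at -0.64 ± 0.19. FN1 was at 0.12 without _x_at and _s_at probe sets. DCN was at 0.48 ± 0.15. Another probe set stood for DCN with a pseudocount of 1, at -0.86, and without DHT control 1, 2 and 3, at -0.24, -0.39 and -0.32. Its main probe set gave 1.49 with that pseudocount and 0.43, 0.47 and 0.55 without those controls. A change that depends so much on the pseudocount is that of a dim probe set, so the size of the DCN change is uncertain. VWF alone of 4 immune and endothelial markers was lower, at -0.79 ± 0.23 (adjusted p = 0.825), and no member was called of 1 basal or 5 neuroendocrine markers (adjusted p = 0.825 for each).

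In all, 2085 of 15913 genes differed, 1064 higher and 1021 lower with DHT, of which 201 rose and 111 fell at least 2-fold. At an unadjusted p under 0.05 there were 4072, and in 7261 genes the arrays of the groups did not overlap, where chance alone gives 20% of genes for 3 arrays against 2. Values as deposited gave 441 genes (317 higher, 124 lower) and median-centred values 979 (706 higher, 273 lower). Without unstimulated replicate 1 or 2 the count was 1175 or 1093. Of the 9 lists called by camera, 5 were called with an estimated correlation as well: those induced and repressed by androgen, cholesterol synthesis, polyamine synthesis and the unfolded protein response. Their adjusted p with it was larger, at 1.68e-06, 0.000586, 0.00215, 0.046 and 0.046 in that order.

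**Figure D2:**
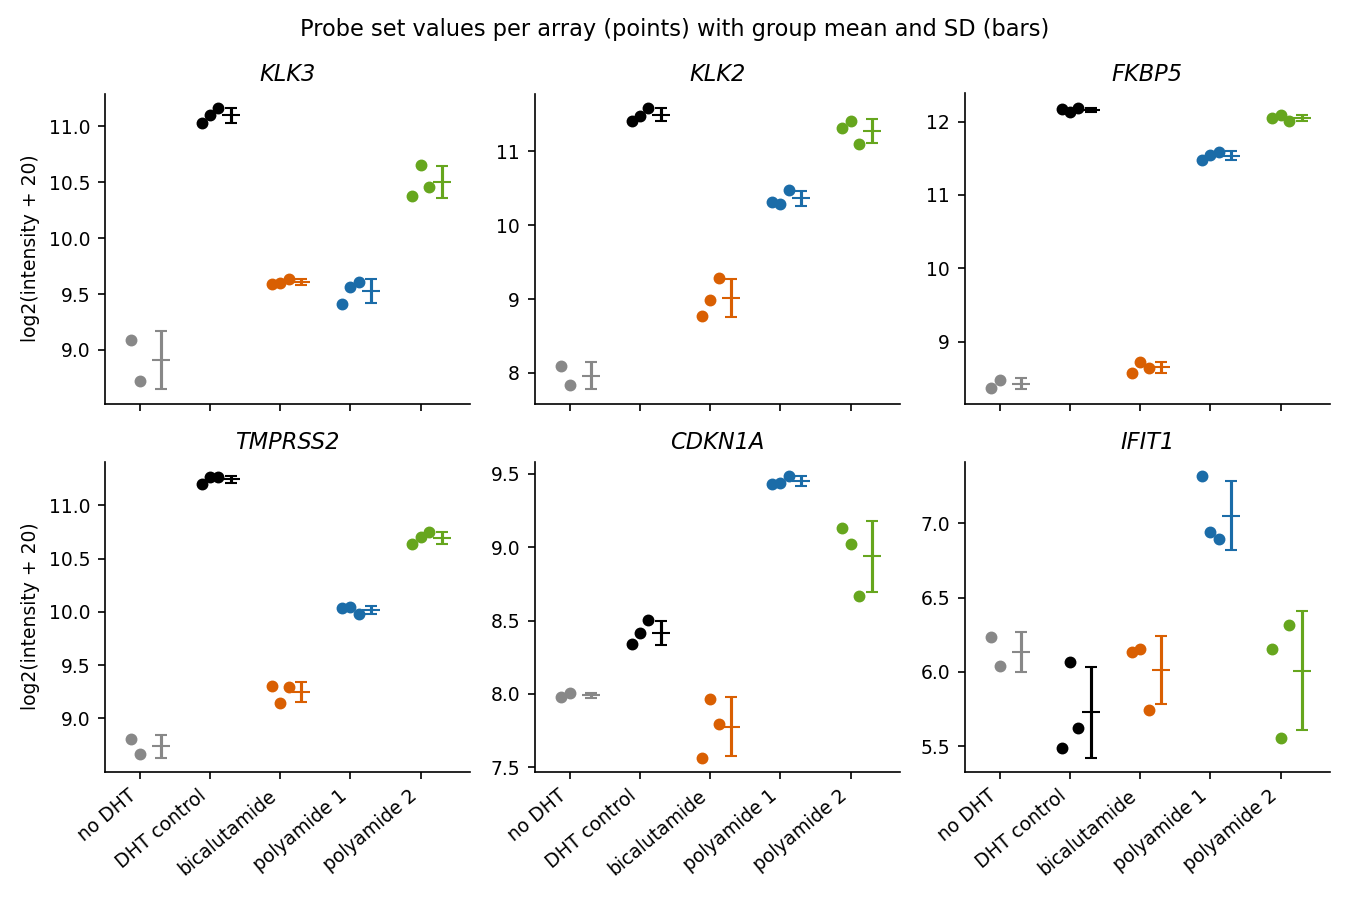
Log2(intensity + 20) of KLK3, KLK2, FKBP5, TMPRSS2, CDKN1A and IFIT1 in the 5 groups, with 1 point per array and bars for the group mean and SD. KLK3 averaged 8.91 without DHT and 11.10 in DHT controls, and CDKN1A and IFIT1 were highest with polyamide 1.

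The second comparison asked how bicalutamide, given 2 h before DHT, altered expression against DHT controls (3 arrays each). STEAP4 changed by -4.27 ± 0.10 (SE, adjusted p = 1.37e-11), FKBP5 by -3.51 ± 0.08, MAF by -3.46 ± 0.13, NCAPD3 by -3.22 ± 0.09 and NDRG1 by -3.16 ± 0.15 on the log2 scale. The kallikrein genes KLK2 and KLK3 changed by -2.48 ± 0.13 and -1.49 ± 0.11, and TMPRSS2 by -2.00 ± 0.08. CCDC141 at -2.78 ± 0.14, the acute-phase protein gene ORM1 at -2.71 ± 0.13, EAF2 at -2.67 ± 0.13 and MICAL1 at -2.53 ± 0.12 were lower as well. Genes that fell with DHT rose with bicalutamide: LRRN1 by 2.85 ± 0.12, OPRK1 by 2.51 ± 0.10, CAMK2N1 by 2.44 ± 0.10, MID1 by 2.42 ± 0.14, GRB10, an adaptor of insulin signalling, by 2.12 ± 0.09 and the metalloprotease MMP16 by 1.97 ± 0.11.

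Of 31 androgen-induced genes 26 fell and 2 rose, or 27 and 2 adjusted over the list alone (median -1.49, camera adjusted p = 3.41e-36). The members that rose were ACP3 at 0.62 and the mediator subunit MED28 at 0.39. Of 12 androgen-repressed genes 8 rose and 0 fell by either adjustment (median 1.71, adjusted p = 2.65e-11). Called members included UGT2B15 at 1.95 ± 0.13 and DDC at 2.03 ± 0.14.

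Of 18 cholesterol genes 13 fell and 0 rose, or 15 and 1 adjusted over the list alone (median -0.55, adjusted p = 2.94e-10). Among them were HMGCS1 at -1.17 ± 0.13, INSIG1 at -0.99 ± 0.10 and SC5D at -0.76 ± 0.09. IDI1 changed by -0.96 ± 0.09, but gave 0.09 without _x_at and _s_at probe sets. Of 10 fatty acid genes 6 fell and 0 rose, or 7 and 0 adjusted over the list alone (adjusted p = 0.000731, and adjusted p = 0.0899 with an estimated correlation), including FADS2 at -0.70 ± 0.12 and FASN at -0.65 ± 0.18. Of 8 polyamine genes 5 fell and 0 rose, or 6 and 1 adjusted over the list alone (adjusted p = 0.000207). The called genes included SMS at -1.51 ± 0.10 and ODC1 at -1.18 ± 0.09. Of 18 hypoxia and glycolysis genes 6 fell and 1 rose, or 7 and 3 adjusted over the list alone (adjusted p = 0.00225, and adjusted p = 0.203 with an estimated correlation). ANKRD37 changed by -1.83 ± 0.09 and HK2 by -1.17 ± 0.11, while EGLN3, an oxygen-sensing hydroxylase, rose by 0.58 ± 0.18.

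Of 33 cell cycle genes 7 rose and 0 fell, or 8 and 0 adjusted over the list alone (median 0.21, adjusted p = 0.0005, and adjusted p = 0.203 with an estimated correlation). Examples were CCNE2 at 0.85 ± 0.14, PCNA at 0.52 ± 0.11 and MCM2 at 0.47 ± 0.13. Of 21 unfolded protein response genes 6 fell and 1 rose, or 8 and 1 adjusted over the list alone (adjusted p = 0.0167, and adjusted p = 0.203 with an estimated correlation). Called members included DNAJB9 at -0.96 ± 0.09 and the amino acid synthesis enzyme ASNS at 0.39. Of 8 luminal markers 4 fell and 1 rose, or 4 and 2 adjusted over the list alone (adjusted p = 0.0231, and adjusted p = 0.0899 with an estimated correlation). Among them were KRT8 at -1.70 ± 0.08, KRT18 at -1.01 ± 0.08, KRT19 at -0.81 ± 0.24 and EPCAM at 0.45.

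Lists without a call by camera were p53 targets (4 higher, 3 lower, or 5 and 3 adjusted over the list alone, adjusted p = 0.254) and immediate early genes (2 higher, 2 lower, or 3 and 4 adjusted over the list alone, adjusted p = 0.393). In these, SESN1 was at 0.96 ± 0.10, TNFRSF10B at -0.96 ± 0.08 and KLF4 at -1.43 ± 0.10. NF-kB targets had 0 higher and 2 lower by either adjustment (adjusted p = 0.153), NFKBIA at -1.08 ± 0.13 and TNFAIP3 at -0.79 ± 0.15, and NFKBIA gave 0.09 without _x_at and _s_at probe sets. Interferon genes had 1 higher and 2 lower, or 2 and 2 adjusted over the list alone (adjusted p = 0.293). Stromal markers had 2 higher by either adjustment (adjusted p = 0.199), COL3A1 at 0.79 ± 0.14 and FN1 at 0.98 ± 0.17, and FN1 gave -0.15 without _x_at and _s_at probe sets. Camera called the stromal list higher without DHT control 2 (adjusted p = 0.0436) or 3 (0.0378). Heat shock (1 higher, HSPB1 at 0.32 ± 0.08, adjusted p = 0.837), histones (1 lower, H2BC21 at -0.59 ± 0.11, adjusted p = 0.743) and ribosome biogenesis (FBL at 0.32 ± 0.08, WDR43 at -0.33 ± 0.10, adjusted p = 0.703) had few called members. Ribosomal proteins (adjusted p = 0.82), basal (adjusted p = 0.761), neuroendocrine (adjusted p = 0.703) and immune and endothelial markers (adjusted p = 0.837) had 0.

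In all, 2554 genes differed, 1294 higher and 1260 lower, with 89 up and 166 down at least 2-fold, 4481 at an unadjusted p under 0.05 and 5576 with arrays that did not overlap (chance gives 10% for 3 arrays against 3). Values as deposited gave 496 (258 higher, 238 lower) and median-centred values 1048 (508 higher, 540 lower). Of 9 lists called by camera, the androgen, cholesterol and polyamine lists, 4 in all, were called with an estimated correlation. Their adjusted p with it was 2.94e-06 for androgen-induced, 0.000452 for androgen-repressed, 0.000452 for cholesterol and 0.0457 for polyamine genes.

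Set against the 2 unstimulated arrays, the 3 bicalutamide arrays differed in 0 genes in limma, with a lowest adjusted p = 0.0535, 918 genes at an unadjusted p under 0.05 and 3833 with arrays that did not overlap (chance gives 20% for 3 arrays against 2). Counts were 5 with a pseudocount of 100, 4 with trend and robust priors, 2 with array weights, 2 with a stricter filter, 1 with median-centred values, 0 with values as deposited and 1 without bicalutamide replicate 1. The androgen-induced list was higher with bicalutamide than without DHT, by a median of 0.17 (adjusted p = 9.09e-13), with 0 members called, or 9 higher and 1 lower adjusted over the list alone. The androgen-repressed list was lower (median -0.19, adjusted p = 0.0143, and adjusted p = 0.0803 with an estimated correlation), with 0 members called, or 1 lower adjusted over the list alone. That call was lost without bicalutamide replicate 3 (0.0711) or unstimulated replicate 2 (0.101) and with values as deposited (0.243). Of the other lists, whose test in this comparison was not planned, the cholesterol list was lower (median -0.15, adjusted p = 0.0141) and the unfolded protein response list higher (median 0.11, adjusted p = 0.000425). DHT raised both lists, and with an estimated correlation neither was called (adjusted p = 0.0803 for each).

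The third comparison set polyamide 1, present for 48 h before DHT, against DHT controls (3 arrays each). IMMP2L, a mitochondrial inner membrane peptidase subunit, fell most, with a change of -3.21 ± 0.16 on the log2 scale (SE, 9.23-fold lower, adjusted p = 4.55e-08). The receptor phosphatase PTPRM changed by -2.52 ± 0.10, the trafficking protein gene LRBA by -2.50 ± 0.12, the methyltransferase SMYD3 by -2.23 ± 0.11, the BMP receptor BMPR1B by -2.23 ± 0.13, LPP by -2.20 ± 0.11, the phosphodiesterase PDE10A by -2.11 ± 0.09, ankyrin ANK3 by -2.01 ± 0.09 and the kinase PRKCA by -1.92 ± 0.10. The steroid-metabolising reductases AKR1C1, AKR1C3 and AKR1C2 rose by 1.83 ± 0.15, 1.82 ± 0.13 and 1.59 ± 0.16. AKR1C1 gave -0.02 on the probe set used when _x_at and _s_at probe sets were left out. Other rises were PLAAT4 at 1.61 ± 0.15, the oxidoreductase TP53I3 at 1.56 ± 0.14, ZPLD1 at 1.46 ± 0.10 and the sialyltransferase ST6GALNAC1 at 1.35 ± 0.11.

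Androgen-induced genes fell: 24 of 31, with 1 higher, or 25 and 1 adjusted over the list alone (median -0.67, camera adjusted p = 7.55e-18). KLK3 changed by -1.57 ± 0.11 (adjusted p = 8.85e-07), NDRG1 by -1.58 ± 0.15, STEAP4 by -1.41 ± 0.10, ACP3 by -1.27 ± 0.13, TMPRSS2 by -1.22 ± 0.08, KLK2 by -1.14 ± 0.13 and FKBP5 by -0.63 ± 0.08, and MED28 rose by 0.67. The change of ACP3 was in the direction in which DHT moved it (-1.10), not a reversal. Of 12 androgen-repressed genes 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.23, adjusted p = 0.0245, and adjusted p = 0.106 with an estimated correlation). UGT2B15 rose by 1.04 ± 0.13, UGT2B28 by 0.87 ± 0.15 and BCHE by 0.74 ± 0.12, while TMEFF2 changed by -1.20 ± 0.08.

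Of 21 p53 target genes 13 rose and 0 fell, or 16 and 0 adjusted over the list alone (median 0.51, adjusted p = 5.75e-12). The death receptor gene FAS rose by 1.16 ± 0.09, the cell cycle inhibitor CDKN1A by 1.03 ± 0.13 and GADD45A by 1.02 ± 0.10, and FAS gave -0.10 without _x_at and _s_at probe sets. Of 15 interferon genes 9 rose and 0 fell, or 12 and 0 adjusted over the list alone (median 0.48, adjusted p = 6.85e-09). The called genes included IFIT2 at 1.40 ± 0.14, IFI6 at 1.33 ± 0.14, IFIT1 at 1.33 ± 0.20 and IFI44 at 1.19 ± 0.14. Of 8 heat shock genes 3 rose and 0 fell, or 4 and 0 adjusted over the list alone (adjusted p = 0.0017, and adjusted p = 0.0907 with an estimated correlation): HSPH1 at 0.60 ± 0.10, HSPB1 at 0.50 ± 0.08 and BAG3 at 0.45 ± 0.10. Of 8 histone genes 3 rose and 1 fell, or 4 and 1 adjusted over the list alone (adjusted p = 0.0159, and adjusted p = 0.106 with an estimated correlation). Examples were H2BC5 at 0.97 ± 0.12 and H2BC21 at -0.38 ± 0.11. Of 9 immediate early genes 3 rose and 1 fell, or 4 and 1 adjusted over the list alone (adjusted p = 0.048, and adjusted p = 0.167 with an estimated correlation). Called members included DUSP1 at 0.84 ± 0.09, JUN at 0.72 ± 0.12 and EGR1 at -1.13 ± 0.12. This last call was lost with values as deposited (0.199), without a filter (0.116), without polyamide 1 replicate 1 (0.0692) or 3 (0.0933), and without DHT control 1 (0.0621), 2 (0.05) or 3 (0.0526).

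Of 18 hypoxia and glycolysis genes 7 fell and 0 rose, or 8 and 1 adjusted over the list alone (adjusted p = 0.000212, and adjusted p = 0.111 with an estimated correlation), including PDK1 at -1.33 ± 0.18, HK2 at -0.98 ± 0.11, ANKRD37 at -0.88 ± 0.09 and P4HA1 at -0.76 ± 0.14. Of 10 fatty acid genes 2 fell and 0 rose, or 3 and 0 adjusted over the list alone (adjusted p = 0.000758, and adjusted p = 0.0907 with an estimated correlation): ACACA at -0.98 ± 0.11 and ELOVL5 at -0.50 ± 0.08. Of 21 unfolded protein response genes 5 fell and 2 rose, or 6 and 2 adjusted over the list alone (adjusted p = 0.0296, and adjusted p = 0.167 with an estimated correlation). Among them were EDEM1 at -1.04 ± 0.17, SEL1L at -0.71 ± 0.10 and XBP1 at -0.46 ± 0.12. Without DHT control 3 that list had an adjusted p = 0.0549. Of 8 polyamine genes 3 fell and 0 rose by either adjustment (adjusted p = 0.0245, adjusted p = 0.15 with an estimated correlation, and 0.0549 with values as deposited): ODC1 at -0.68 ± 0.09, SAT1 at -0.60 ± 0.13 and SMS at -0.52 ± 0.10.

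Camera made no call for cholesterol genes (1 higher, 2 lower by either adjustment, adjusted p = 0.923; median -0.03, mean 0.0004), where TM7SF2 rose by 0.76 ± 0.10 and INSIG1 changed by -0.35 ± 0.10. The cell cycle list had 2 higher and 3 lower by either adjustment (adjusted p = 0.875). The called genes included CCNE2 at 0.54 ± 0.14 and CENPF at -0.50 ± 0.16. Luminal markers had 1 higher and 3 lower by either adjustment (adjusted p = 0.0984): GRHL2 at -0.76 ± 0.09, HOXB13 at -0.70 ± 0.11, KRT8 at -0.45 ± 0.08 and EPCAM at 0.46 ± 0.08. Stromal markers had 1 higher and 1 lower, or 2 and 1 adjusted over the list alone (adjusted p = 0.409, but 0.0341 without DHT control 2 and 0.0431 without DHT control 3). Examples were COL1A1 at 0.92 ± 0.13 and DCN at -0.61 ± 0.13. The other probe set of DCN gave 0.54 with a pseudocount of 1 and 0.10, 0.25 and 0.18 without DHT control 1, 2 and 3, where the main probe set of DCN gave -2.02, -0.56, -0.60 and -0.68. VWF was at 0.85 ± 0.21 in the immune and endothelial list (adjusted p = 0.29), SCG2 at -0.40 ± 0.10 in the neuroendocrine list (adjusted p = 0.409) and NOP2 at 0.50 ± 0.10 in the ribosome biogenesis list (adjusted p = 0.409). NF-kB targets (adjusted p = 0.923, median -0.09 with camera's direction upward), ribosomal proteins (adjusted p = 0.873) and basal markers (adjusted p = 0.923) had 0 called members.

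In all, 2341 genes differed, 1072 higher (45.8%) and 1269 lower, with 37 up and 156 down at least 2-fold, 4278 at an unadjusted p under 0.05 and 5316 with arrays that did not overlap (chance gives 10%). Values as deposited gave 507 (54 higher, 453 lower) and median-centred values 1003 (200 higher, 803 lower), so that the balance of rises and falls depended on the scaling. Of 11 lists called by camera, the 3 for androgen-induced genes, p53 targets and interferon genes were called with an estimated correlation (adjusted p = 6.3e-05, 0.0115 and 0.0115). Against the unstimulated arrays, polyamide 1 had 26 of 31 androgen-induced genes higher and 2 lower (median 1.05, adjusted p = 1.13e-24) and 1 of 12 androgen-repressed genes higher and 9 lower (median -1.24, adjusted p = 2.27e-10).

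The fourth comparison set polyamide 2, also present for 48 h before DHT, against DHT controls (3 arrays each). The heparan sulfate proteoglycan gene GPC6 fell most, with a change of -1.94 ± 0.12 on the log2 scale (SE, adjusted p = 3.25e-06). SMYD3 changed by -1.71 ± 0.11, the GDP-mannose dehydratase GMDS by -1.50 ± 0.15, IMMP2L by -1.50 ± 0.16, LPP by -1.46 ± 0.11, the spindle checkpoint gene MAD1L1 by -1.44 ± 0.10 and the potassium channel gene KCNQ1 by -1.30 ± 0.12. The largest rises were ST6GALNAC1 at 1.28 ± 0.11, LXN, a carboxypeptidase inhibitor, at 1.20 ± 0.12, the receptor phosphatase PTPRO at 1.07 ± 0.23, UGT2B28 at 1.05 ± 0.15, the chemokine receptor CXCR4 at 0.92 ± 0.13, TP53I3 at 0.86 ± 0.14, the non-coding RNA DRAIC at 0.83 ± 0.14 and IGFBP3 at 0.82 ± 0.09.

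Among androgen-induced genes 9 of 31 fell and 2 rose, or 11 and 3 adjusted over the list alone (median -0.18, camera adjusted p = 0.000298). ACP3 changed by -1.14 ± 0.13, the ion channel gene TRPM8 by -0.99 ± 0.11, PMEPA1 by -0.91 ± 0.16, KLK3 by -0.60 ± 0.11 (adjusted p = 0.00693) and TMPRSS2 by -0.55 ± 0.08, while SGK1 rose by 0.60 ± 0.12 and HPGD by 0.51. ACP3 had also changed by -1.10 with DHT, so its change with polyamide 2 was not a reversal. KLK2 was at -0.22 (95% interval -0.51 to 0.06, adjusted p = 0.404) and FKBP5 at -0.11 (-0.28 to 0.06, adjusted p = 0.504), neither of them called. As a mean over its probe sets FKBP5 was at 0.17. Of 12 androgen-repressed genes 5 fell and 1 rose, or 5 and 2 adjusted over the list alone (median -0.12, adjusted p = 0.0596). Called members included SI at -0.84 ± 0.12, TMEFF2 at -0.78 ± 0.08 and BCHE at -0.59 ± 0.12.

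Of 21 p53 target genes 5 rose and 0 fell, or 6 and 0 adjusted over the list alone (median 0.18, adjusted p = 7.53e-05, and adjusted p = 0.122 with an estimated correlation). Among them were GADD45A at 0.74 ± 0.10, CDKN1A at 0.52 ± 0.13 and the repair gene XPC at 0.51 ± 0.13. Of 15 interferon genes 2 rose and 0 fell, or 4 and 0 adjusted over the list alone (median 0.23, adjusted p = 0.000298, and adjusted p = 0.122 with an estimated correlation): IFI6 at 0.72 ± 0.14 and IFIT2 at 0.60 ± 0.14. Of 9 NF-kB targets 1 rose and 0 fell by either adjustment, NFKB2 at 0.55 ± 0.11 (adjusted p = 0.0484, and adjusted p = 0.144 with an estimated correlation). That call was lost without a filter (0.0885), without polyamide 2 replicate 1 (0.109) and without DHT control 1 (0.0777) or 2 (0.0629). Of 21 unfolded protein response genes 2 fell and 0 rose, or 3 and 0 adjusted over the list alone (adjusted p = 0.0484, and adjusted p = 0.23 with an estimated correlation): SEL1L at -0.46 ± 0.10 and ASNS at -0.30 ± 0.08. That call was lost without polyamide 2 replicate 1 (0.404) and without DHT control 1 (0.0601) or 3 (0.104).

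Camera made no call for immediate early genes (1 higher, 1 lower, or 4 and 1 adjusted over the list alone, adjusted p = 0.0581, but 0.0479 with a replicate block). The called genes included DUSP1 at 0.53 ± 0.09 and EGR1 at -0.65 ± 0.12. HK2 was at -0.61 ± 0.11 in the hypoxia and glycolysis list (1 lower, or 2 adjusted over the list alone, adjusted p = 0.163), HOXB13 at -0.54 ± 0.11 in the luminal list (adjusted p = 0.281) and TM7SF2 at 0.48 ± 0.10 in the cholesterol list (adjusted p = 0.377). Fatty acid genes had 0 called, or 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.382). No member was called over all genes in the cell cycle (adjusted p = 0.377), histone (0.0684), heat shock (0.325), polyamine (0.438), ribosome biogenesis (0.559) and ribosomal protein lists (0.8), nor among basal (0.377), neuroendocrine (0.508), stromal (0.8) and immune and endothelial markers (0.943; median -0.02, mean 0.04).

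In all, 693 genes differed, 170 higher (24.5%) and 523 lower, with 4 up and 38 down at least 2-fold, 2975 at an unadjusted p under 0.05 and 3606 with arrays that did not overlap (chance gives 10%). Values as deposited gave 172 genes (4 higher, 168 lower) and median-centred values 492 (22 higher, 470 lower). The median change of all genes was -0.154 and -0.124 under these scalings and -0.00775 with quantile normalised values, so the changes above are relative to the other genes. Counts were 254 from a fit of the 2 groups alone, 1233 with a pseudocount of 100, 436 without polyamide 2 replicate 3, and 328, 374 and 433 without DHT control 1, 2 and 3. Of 5 lists called by camera, only the androgen-induced list was called with an estimated correlation (adjusted p = 0.023). Against the unstimulated arrays, polyamide 2 had 27 of 31 androgen-induced genes higher and 1 lower (median 1.74, adjusted p = 1.85e-33) and 1 of 12 androgen-repressed genes higher and 9 lower (median -1.97, adjusted p = 2.27e-10).

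**Figure D3:**
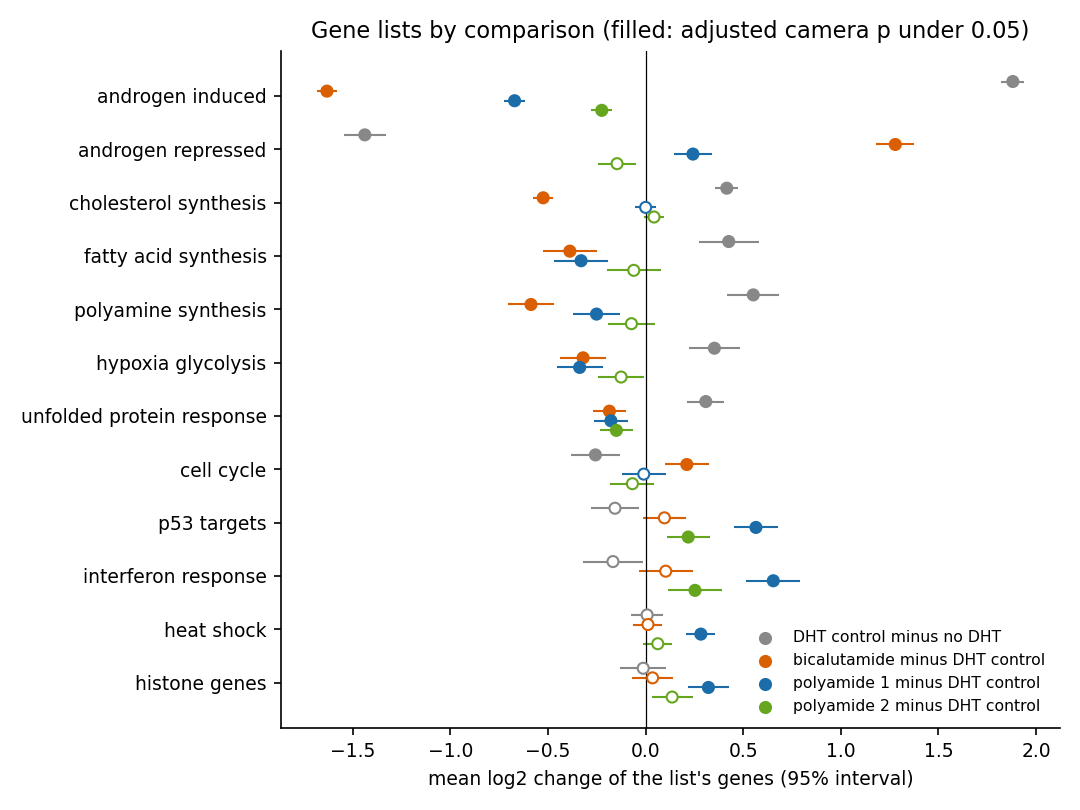
Mean log2 change of the genes of 12 lists in 4 comparisons, with 95% intervals as lines and filled points where the adjusted camera p was under 0.05. The androgen-induced list had means of 1.88 with DHT, -1.63 with bicalutamide, -0.67 with polyamide 1 and -0.22 with polyamide 2.

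The polyamides shared dose and time, so a direct comparison of polyamide 1 with polyamide 2 (3 arrays each) asked where the compounds differ. The cholinesterase gene BCHE was higher with polyamide 1 by 1.33 ± 0.12 on the log2 scale (SE, 95% interval 1.08 to 1.59, adjusted p = 0.000109), as were ZPLD1 by 1.32 ± 0.10, the phosphatase PTPRR by 1.28 ± 0.15, AKR1C3 by 1.28 ± 0.13, AKR1C1 by 1.26 ± 0.15, IFIT1 by 1.05 ± 0.20 and ENC1 by 1.01 ± 0.09. Lower with polyamide 1 were IMMP2L at -1.71 ± 0.16, ANK3 at -1.37 ± 0.09, LRBA at -1.32 ± 0.12, PTPRM at -1.30 ± 0.10, NDRG1 at -1.27 ± 0.15, the kinase STK39 at -1.12 ± 0.11 and BMPR1B at -1.07 ± 0.13. KLK3 was lower with polyamide 1, with a difference of -0.97 (-1.21 to -0.74, adjusted p = 0.000447), as were KLK2 at -0.92 (-1.20 to -0.63), TMPRSS2 at -0.67 (-0.85 to -0.50) and FKBP5 at -0.52 (-0.69 to -0.35). KLK2 gave 0.11 on the probe set used when _x_at and _s_at probe sets were left out.

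Among androgen-induced genes 15 of 31 were lower with polyamide 1 and 1 was higher, or 22 and 1 adjusted over the list alone (mean -0.45, 95% interval -0.50 to -0.39, camera adjusted p = 8.38e-19). Of 12 androgen-repressed genes 6 were higher and 1 lower, or 7 and 1 adjusted over the list alone (mean 0.39, 0.29 to 0.49, adjusted p = 0.000155), including CAMK2N1 at 0.88 ± 0.10 and SI at 0.87 ± 0.12. Of 21 p53 target genes 7 were higher and 0 lower, or 9 and 0 adjusted over the list alone (mean 0.35, 0.24 to 0.46, adjusted p = 9.02e-09). Examples were FAS at 0.79 ± 0.09, DDB2 at 0.74 ± 0.15 and GDF15 at 0.59 ± 0.10. Of 15 interferon genes 6 were higher and 0 lower, or 8 and 0 adjusted over the list alone (mean 0.40, 0.26 to 0.54, adjusted p = 1.96e-06). Called members included IFI44 at 0.98 ± 0.14, IFIT2 at 0.80 ± 0.14 and ISG15 at 0.69 ± 0.11. Of 18 hypoxia and glycolysis genes 4 were lower and 0 higher, or 8 and 1 adjusted over the list alone (adjusted p = 0.000211, and adjusted p = 0.116 with an estimated correlation). Among them were ANKRD37 at -0.76 ± 0.09 and lactate dehydrogenase LDHA at -0.46 ± 0.10.

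Of 10 fatty acid genes 2 were lower and 0 higher by either adjustment (adjusted p = 0.000286, and adjusted p = 0.0597 with an estimated correlation): ACACA at -0.66 ± 0.11 and FADS2 at -0.59 ± 0.12. Of 8 heat shock genes 2 were higher and 0 lower, or 4 and 0 adjusted over the list alone (adjusted p = 0.00124, and adjusted p = 0.0597 with an estimated correlation): HSPH1 at 0.45 ± 0.10 and HSPB1 at 0.34 ± 0.08. Of 8 polyamine genes 2 were lower and 0 higher, or 4 and 1 adjusted over the list alone (adjusted p = 0.0224, adjusted p = 0.144 with an estimated correlation, 0.132 with values as deposited, and 0.127 without polyamide 2 replicate 2): SMS at -0.51 ± 0.10 and ODC1 at -0.44 ± 0.09. NF-kB targets were lower as a list (median -0.25, adjusted p = 0.0242, and adjusted p = 0.0776 with an estimated correlation) with 0 members called by either adjustment. That call was lost without a filter (0.113), without polyamide 1 replicate 1 (0.074) or 2 (0.0609) and without polyamide 2 replicate 1 (0.0934).

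A difference between the polyamides was not detected for cholesterol genes (mean -0.04, -0.10 to 0.01, adjusted p = 0.343), cell cycle genes (mean 0.06, -0.05 to 0.17, adjusted p = 0.56) or ribosomal proteins (mean 0.02, -0.02 to 0.05, adjusted p = 0.851), and these intervals leave out differences beyond their bounds only under quantile normalisation. The median difference of all genes was 0.016 under it, 0.0584 with values as deposited and 0.0745 with median-centred values, and the last 2 exceed some of these bounds. PCNA was called among cell cycle genes, at 0.42 ± 0.11 (3 higher adjusted over the list alone). The unfolded protein response list had 1 higher and 1 lower, or 1 and 2 adjusted over the list alone (adjusted p = 0.403), ASNS at 0.62 ± 0.08 and DNAJB9 at -0.44 ± 0.09. Histones had 2 higher and 0 lower, or 3 and 1 adjusted over the list alone (adjusted p = 0.139, 0.0301 with values as deposited, and 0.0229 without polyamide 2 replicate 3), H2AC8 at 0.73 ± 0.17 and H2BC5 at 0.58 ± 0.12. Immediate early genes had IER2 at 0.40 ± 0.09 and EGR1 at -0.49 ± 0.12 (3 and 1 adjusted over the list alone, adjusted p = 0.607; median -0.02, mean 0.03). Luminal markers had 1 higher and 2 lower, or 2 and 2 adjusted over the list alone (adjusted p = 0.296), GRHL2 at -0.56 ± 0.09, KRT8 at -0.37 ± 0.08 and EPCAM at 0.31 ± 0.08. Stromal markers had COL1A1 at 0.61 ± 0.13 and DCN at -0.58 ± 0.13 (adjusted p = 0.296, but 0.0325 without polyamide 2 replicate 2). Ribosome biogenesis (adjusted p = 0.51), basal (0.403), neuroendocrine (0.607) and immune and endothelial lists (0.139, but 0.0246 without polyamide 1 replicate 1) had 0 called members.

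In all, 637 genes differed between the polyamides, 324 higher and 313 lower with polyamide 1, with 8 up and 10 down at least 2-fold, 2894 at an unadjusted p under 0.05 and 3354 with arrays that did not overlap (chance gives 10%). This count depended on the processing: 12 (6 higher, 6 lower) with values as deposited, 83 (52 higher, 31 lower) with median-centred values, 73 from a fit of the 2 groups alone, 388 without _x_at and _s_at probe sets, 411 with array weights, 984 with trend and robust priors and 1157 with a pseudocount of 100. It was 276, 362 and 335 without polyamide 1 replicate 1, 2 and 3, and 415 and 416 without polyamide 2 replicate 2 and 3. Of 9 lists called by camera, the 4 for androgen-induced genes, androgen-repressed genes, p53 targets and interferon genes were called with an estimated correlation (adjusted p = 5.05e-05, 0.0249, 0.0249 and 0.0249).

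The 201 genes that rose at least 2-fold with DHT were then followed through the treatments. They were selected on these DHT controls, so their fall is not independent evidence of its direction. Bicalutamide lowered 199 of them (99.0%, Wilson interval 96.5 to 99.7), polyamide 1 lowered 130 (64.7%, 57.9 to 71.0) and raised 2, and polyamide 2 lowered 33 (16.4%, 11.9 to 22.2) and raised 5. The median share of the DHT change reversed was 90.9% with bicalutamide, 35.0% with polyamide 1 and 8.34% with polyamide 2. These shares were not adjusted for gene span, which is weighed in the closing sections. In 100 simulations a group with no change shared its controls with the DHT comparison. There, 218 to 254 genes counted as DHT-induced, not these 201. Of the simulated genes 0 were called lower, and the median share reversed was 1.55% (-0.120 to 3.15). That range does not cover changes of scaling, given below. With control 1, 2 or 3 kept out of the selection and used alone for the treatment, the median shares were 88.7%, 87.0% and 90.6% for bicalutamide, 34.2%, 32.0% and 35.6% for polyamide 1, and 7.62%, 8.55% and 10.4% for polyamide 2. With values as deposited the shares lowered were 80.5%, 33.9% and 9.16% and the medians 79.3%, 43.0% and 26.5%, and with no fold limit the shares were 81.3%, 33.7% and 8.84%. Bicalutamide was given for a different time before DHT than the polyamides. Polyamide 1 was lower than polyamide 2 over these genes by a mean of -0.38 (95% interval -0.43 to -0.33), with 70 genes lower and 0 higher. Camera gave p = 4.74e-46 with the preset correlation and p = 2.28e-06 with an estimated correlation. This difference was not tested directly against gene span, and medians by span are given in the closing sections. Polyamide 1 was above bicalutamide by a mean of 0.83, with 159 genes higher and 4 lower (camera p = 9.63e-55 with the preset and 1.06e-06 with an estimated correlation). Polyamide 2 was above bicalutamide by a mean of 1.21, with 186 higher and 0 lower (camera p = 7.06e-95 with the preset and 9.15e-08 with an estimated correlation). Of the 111 genes that fell at least 2-fold with DHT, bicalutamide raised 111, polyamide 1 raised 36 (32.4%) and lowered 16, and polyamide 2 raised 5 (4.5%) and lowered 21. Their median shares reversed were 86.2%, 14% and -9.27%, and the last was 4.60% with no fold limit. With 1 array omitted, the share for polyamide 2 ran from -11.2% (polyamide 2 replicate 1) to -4.89% (DHT control 2).

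**Figure D4:**
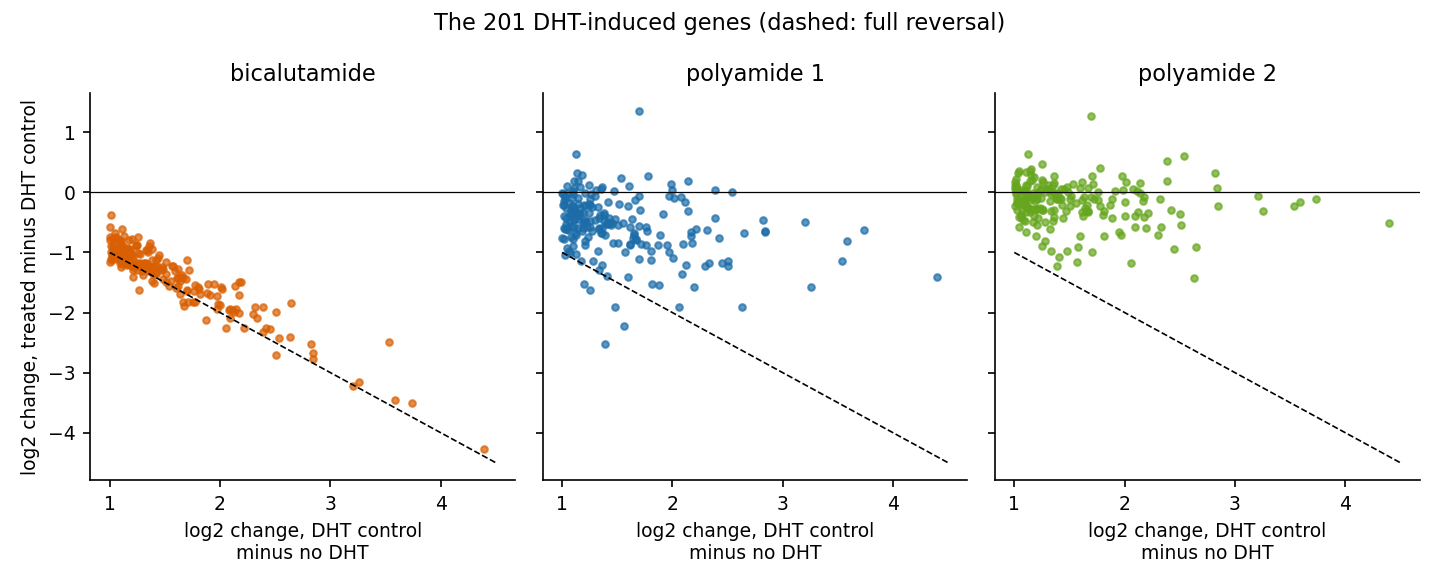
Log2 change with each treatment against DHT controls (vertical axis) over the log2 change with DHT (horizontal axis) for the 201 DHT-induced genes, 1 panel per treatment, with a dashed line at full reversal. Points lay near the dashed line for bicalutamide (median 90.9% reversed), partway for polyamide 1 (35.0%) and near 0 for polyamide 2 (8.34%).

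Across all genes, which are not independent replicates, log2 changes against the same DHT controls were correlated. The change without DHT and that with bicalutamide gave r = 0.875. Simulated unchanged groups, with controls shared in the same way, gave 0.184 with the change without DHT (0.157 to 0.203) and 0.501 with each other (0.482 to 0.520). Polyamide 1 correlated with the change without DHT at 0.355, and polyamide 2 at 0.173. Bicalutamide correlated with polyamide 1 at 0.362 and with polyamide 2 at 0.179, and the polyamides with each other at 0.684. The simulated groups carry noise alone, and changes of a treatment's own lower r, so covariances are the closer comparison. Covariances were 0.107 for no DHT with bicalutamide, 0.0400 with polyamide 1 and 0.0148 with polyamide 2, 0.0378 and 0.0141 for bicalutamide with polyamide 1 and 2, and 0.0498 for the polyamides. Simulated covariances were 0.0107 with the change without DHT (0.00927 to 0.0119) and 0.0107 between unchanged groups (at most 0.0114).

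In a division chosen after these values were seen, 1 control served one change and the other 2 served the other, averaged over the 6 such divisions. The correlations were then 0.714 for no DHT with bicalutamide, 0.235 with polyamide 1 and 0.0438 with polyamide 2. They were 0.233 for bicalutamide with polyamide 1 and 0.0392 with polyamide 2, and 0.457 for the polyamides (0.442 to 0.484 over divisions). The covariance of the polyamides was 0.0392 (0.0377 to 0.0403), and those of polyamide 2 with no DHT and bicalutamide were 0.00428 and 0.00357. A single control is noisier than a mean of 3, which lowers r, and no division of 3 controls leaves 2 in each part. Both polyamides raised 127 genes, where independent calls would give 11.5, and both lowered 431, where they would give 41.7, and the shared controls add to these overlaps.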

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

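The tests within the brighter 3 of 5 bins of intensity and against other genes of like span were chosen only after the results were seen. So were the gene span correlations and the counts of unnamed probe sets under other scalings. The androgen lists were planned to be set against the unstimulated arrays. The limits for judging from them whether treated cells received DHT were set after the results were seen. The use of the cholesterol and unfolded protein response lists for this was also chosen then.

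Probe sets that the probe table used here does not name gave a signal outside the gene comparisons. Of 6269 tested in limma with Benjamini-Hochberg adjustment, 141 were called with DHT (84 higher, 57 lower), 178 with bicalutamide (76 higher, 102 lower), 115 with polyamide 1 (50 higher, 65 lower), 2 with polyamide 2 (both lower) and 12 between the polyamides (9 higher with polyamide 1, 3 lower). Values as deposited gave 55, 68, 23, 1 and 0 in the same order, and median-centred values 105, 148, 67, 2 and 5. Their identity was not examined.

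Genes with long spans in RefSeq annotation of GRCh38.p14 were lower with both polyamides: of 614 genes of 300 kb or more, polyamide 1 lowered 249 (40.6%) and raised 9, polyamide 2 lowered 161 (26.2%) and raised 2, and bicalutamide lowered 49 (7.98%) and raised 72, while of 3942 genes under 10 kb polyamide 1 lowered 97 (2.46%) and polyamide 2 lowered 29 (0.736%). The shared DHT controls are argued against as the cause, since the Spearman correlation across genes of span with polyamide 1 was -0.232 against those controls and -0.240 against the unstimulated arrays. Dimness of long genes on the array is argued against in the brighter 3 of 5 equal bins of genes by mean intensity, where the weakest correlation was -0.335, while the bin below gave -0.116 and the dimmest bin 0.00517, no correlation, so dimness stays open in that bin. Exposure to a DNA-binding polyamide is a candidate explanation as a hypothesis, since the correlation was -0.243 with polyamide 2 and 0.0935 with bicalutamide against the same controls, but polyamides were present for 48 h before DHT and bicalutamide for 2 h, so compound class and length of exposure cannot be told apart. Among the named genes, IMMP2L spans 900 kb, PTPRM 840 kb, LRBA 751 kb and GPC6 1190 kb. The list tests were not adjusted for span. In lists lower with polyamide 1, called members included long genes such as ACACA (322 kb) and PDK1 (169 kb). Short genes such as ANKRD37 (3.88 kb) were among them as well. Long genes were also lower with polyamide 1 than with polyamide 2 (Spearman correlation -0.077). Of genes of 300 kb or more, 87 (14.2%) were lower with polyamide 1 and 9 higher. Under 10 kb, 28 (0.71%) were lower and 67 higher. Whether span accounts for the difference between the polyamides over DHT-induced genes was not tested directly, and medians by span are given below.

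The fall of DHT-induced genes with polyamide 1 was weighed against span alone, since 111 of the 201 genes lie in the longest of 3 equal groups of genes by span. Those in the shortest group had a median change of -0.335 (95% interval -0.583 to -0.0643, 40 genes). The median lay past the limit against span alone that was written for it beforehand. The upper end of its interval did not, so on its own this value was taken to leave span open. Set against other genes in the shortest group, the DHT-induced genes were lower by a median difference of -0.376 (-0.630 to -0.136), which argues against span as the whole cause. Intervals in this paragraph come from resampled genes, treat genes as independent and hold no variation between arrays. The DHT-induced genes were also selected on the DHT controls used for the change. DHT-induced genes in the longest group had a median of -0.628, so that span may still account for part of the fall. With polyamide 2, DHT-induced genes had medians of -0.0339, -0.0269 and -0.222 in the shortest, middle and longest groups. Other genes had medians of 0.0335, 0.0152 and -0.0888. The fall with polyamide 2 thus lay mainly in the longest group, where other genes were lower as well. It was not tested against span. With polyamide 1 DHT-induced genes had medians of -0.335, -0.344 and -0.628, with upper interval ends of -0.0643, -0.241 and -0.57. Other genes had 0.0411, 0.0563 and -0.0793. In each group DHT-induced genes were lower with polyamide 1 than with polyamide 2, and other genes were not. This argues against span as the whole cause of the difference between the polyamides over DHT-induced genes. No interval was computed for that difference by group.

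The sample descriptions call the treated cells not stimulated with DHT, and the series design says that they were, but the androgen-induced list lay above the unstimulated arrays by a median of 1.05 with polyamide 1 and 1.74 with polyamide 2, and the lower of these argues against polyamide cultures without DHT. For bicalutamide, limma called 0 genes against the unstimulated arrays (918 at an unadjusted p under 0.05, and 1 to 5 genes under the other settings that called any), a count that a full block by the drug and absence of DHT both predict and that alone cannot tell them apart. The androgen-induced list was nevertheless higher with bicalutamide by a mean of 0.248 (95% interval 0.189 to 0.308, camera adjusted p = 9.09e-13, or 0.000256 with an estimated correlation, and 1.74e-11 with values as deposited), which argues against cultures without DHT in which the drug had no effect of its own. The cholesterol list, which DHT raised, was however lower with bicalutamide than without DHT (median -0.147, adjusted p = 0.0141, and 0.0803 with an estimated correlation), which residual DHT action does not predict, while the unfolded protein response list, also raised by DHT, was higher (median 0.108, adjusted p = 0.000425, and 0.0803 with an estimated correlation), which it does predict. Whether bicalutamide alone raises these genes slightly was not tested, since by the design no culture had the drug without DHT.

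Each comparison of 3 arrays with 3 allows 10 splits of the 6 arrays, too few for a share under 0.05. The real split gave 2554 genes for bicalutamide, 2341 for polyamide 1, 693 for polyamide 2 and 637 between the polyamides, and the highest of the other splits gave 0, 0, 1 and 1. In each case 1 of the 10 splits, the real one, gave as many genes. Every other split mixes the 2 treatments within a group, which adds their difference to the residual spread. Low counts there follow from that mixing and do not measure how many calls arise without an effect.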

How the results depend on the processing

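The values as deposited for the lists, the DHT-induced genes and the correlations, all settings of the gene count of bicalutamide against unstimulated arrays, the division of controls, the main probe set of DCN, and settings for gene spans, NRF2 targets and unnamed probe sets were added after seeing the data. Among named genes, 5237 results under other settings kept direction and call, 823 kept direction and lost the call, and 18 changed direction. Fixed lists other than those for androgen kept their side of the threshold 942 times, lost a call 47 times and gained one 25 times. A change of direction with a call in either setting occurred 0 times. Changes of direction with no call in either setting were counted among the 942. Fry, which does not set a list against other genes, called some lists that camera did not. With DHT these were p53 targets (adjusted p = 0.0453, lower), NF-kB targets (0.0126, higher) and immediate early genes (0.00957, higher). With bicalutamide they were NF-kB targets (0.000917, lower), immediate early genes (0.00304, lower) and stromal markers (0.00582, higher). With polyamide 1 luminal markers were called lower (0.00024). With polyamide 2 fry called immediate early genes (0.0141) and histones (0.0272) higher and luminal markers lower (0.0116). Between the polyamides it called histones higher (0.0208) and luminal markers lower (0.0358) with polyamide 1. The cause of the shifts below was not tested, except where a fold limit or fewer arrays by construction leave fewer calls.

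Counts of called genes for DHT, bicalutamide, polyamide 1, polyamide 2 and polyamide 1 against 2 were 441, 496, 507, 172 and 12 with values as deposited, and 312, 255, 193, 42 and 18 with a 2-fold limit. Median-centred values gave 979, 1048 and 1003 for the first 3 and 83 between the polyamides. For polyamide 2 the count was 1233 with a pseudocount of 100 and 254 from the 2 groups alone. Between the polyamides it was 1157 and 73 with these settings, 388 without _x_at and _s_at probe sets, 411 with array weights and 984 with trend and robust priors. Bicalutamide against unstimulated arrays gave 5 with a pseudocount of 100, 4 with trend and robust priors, 2 with array weights, 2 with a filter at the median and 1 with median-centred values, against 0.

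With each array omitted in turn, counts ran from 1093 to 1688 for DHT, 1726 to 1993 for bicalutamide, 1649 to 1853 for polyamide 1, 328 to 745 for polyamide 2, 276 to 659 between the polyamides and 0 to 1 for bicalutamide against unstimulated arrays. Where 1 unstimulated array was left, it was assumed to vary like the other groups. Omissions that moved a count over 1.5 times were unstimulated 1 (1175) and 2 (1093) for DHT, DHT control 1 (328), 2 (374) and 3 (433) and polyamide 2 replicate 3 (436) for polyamide 2, polyamide 1 replicates 1 (276), 2 (362) and 3 (335) and polyamide 2 replicates 2 (415) and 3 (416) between the polyamides, and bicalutamide 1 (1) against unstimulated arrays.

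Camera adjusted p of the androgen-induced list ran, on omission of each array, from 6.98e-45 to 1.56e-40 for DHT, 6.24e-38 to 7.99e-35 for bicalutamide, 2.83e-18 to 3.77e-16 for polyamide 1, 4.38e-05 to 0.00991 for polyamide 2, 1.93e-18 to 2.14e-15 between the polyamides, and against unstimulated arrays 1.34e-12 to 1.06e-08 for bicalutamide, 1.12e-25 to 5.98e-24 for polyamide 1 and 3.98e-36 to 6.24e-32 for polyamide 2. That of the androgen-repressed list ran in the same order from 9.2e-13 to 2.43e-11, 1.81e-12 to 8.07e-11, 0.016 to 0.0439, 0.0629 to 0.123, 5.83e-05 to 0.00084, 0.0123 to 0.101, 7.4e-11 to 9.82e-10 and 2.67e-11 to 1.58e-09. For bicalutamide against unstimulated arrays the call was lost without bicalutamide 3 (0.0711) and unstimulated 2 (0.101). With an estimated correlation the repressed list had an adjusted p of 0.106 for polyamide 1 and 0.0803 for bicalutamide against unstimulated arrays, which was 0.054 with fry and 0.243 with values as deposited, and fry gave 0.00234 for polyamide 2.

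DHT-induced genes lowered by bicalutamide, polyamide 1 and polyamide 2 were 80.48%, 33.86% and 9.163% with values as deposited (median reversal 79.27%, 43.04% and 26.46%) and 81.3%, 33.74% and 8.835% with no fold limit (86.23%, 30.01% and 12.36%). As a mean over probe sets bicalutamide lowered 100%, with median reversal of 31.41% by polyamide 1 and 6.008% by polyamide 2. With a control array kept out of the selection and used alone, reversal was 88.67% (control 1) and 86.96% (control 2) for bicalutamide, 31.97% (control 2) for polyamide 1 and 10.42% (control 3) for polyamide 2. Omission of each array gave shares of 97.01 to 98.49%, 56.22 to 60.2% and 11.27 to 16.42% and reversal of 87.64 to 91.79%, 33.4 to 35.95% and 8.258 to 11.21%. For DHT-lowered genes with no fold limit, the reversal by polyamide 2 turned from negative to 4.602%.

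Over DHT-induced genes the camera p, with the preset correlation, ran on omission of an array from 9.26e-46 to 1.62e-36 between the polyamides, 1.97e-56 to 3.86e-51 for polyamide 1 against bicalutamide and 8.47e-94 to 1.31e-88 for polyamide 2 against bicalutamide. Correlations with the change without DHT were 0.853, 0.3852 and 0.2549 for bicalutamide, polyamide 1 and polyamide 2 with values as deposited, and 0.8583 for bicalutamide without a filter. On omission of each control they ran from 0.8763 to 0.8832, 0.3706 to 0.3918 and 0.2057 to 0.233, and those of bicalutamide with polyamide 1 from 0.3834 to 0.3987, with polyamide 2 from 0.2188 to 0.2363, and of the polyamides from 0.7011 to 0.7049. With the controls divided between the changes, the correlations with no DHT were 0.7142, 0.2346 and 0.04381, those of bicalutamide with polyamide 1 and 2 were 0.2329 and 0.03923, and that of the polyamides was 0.457.

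Direction changed for DCN with a pseudocount of 1 (-0.863 with DHT, 0.5401 with polyamide 1) and without DHT control 1, 2 or 3 (-0.2358, -0.3874 and -0.3187 with DHT, 0.1007, 0.2529 and 0.1825 with polyamide 1). In all of these another probe set stood for DCN, and on its main probe set the gene was at 1.49, 0.427, 0.473 and 0.549 with DHT and -2.02, -0.557, -0.602 and -0.68 with polyamide 1. Over all omissions DCN ran from -0.3874 to 0.7001 with DHT and from -0.7237 to 0.2529 with polyamide 1. Without _x_at and _s_at probe sets another probe set stood for the gene, with FN1 at 0.1153 and -0.1482 and IDI1 at -0.09988 and 0.09426 for DHT and bicalutamide, KLK2 at -0.1189 for DHT and 0.1113 between the polyamides, NFKBIA at 0.09156 for bicalutamide, and AKR1C1 at -0.01772 and FAS at -0.1041 for polyamide 1. FKBP5 as a mean over probe sets was at 0.1746 with polyamide 2.

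Replicate numbers did not pair the arrays: of 26 same-number pairs 1 had r over 0.1 (-0.0642 to 0.121), and 6 of 14 arrays correlated best with their own number. With a replicate block the counts were 1866, 2377, 2184, 577 and 534 for the 5 comparisons and 0 for bicalutamide against unstimulated arrays, and median reversal was 89.45% for bicalutamide and 10.41% for polyamide 2.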

Other observations

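Some large changes lay outside the lists. With polyamide 1 the calcium-activated potassium channel gene KCNMA1 changed by -1.91 ± 0.17 on the log2 scale (SE, n = 3 against 3, adjusted p = 7.77e-06) and the phosphatase PTPRR by 1.33 ± 0.15. With polyamide 2 the chondroitin sulfate enzyme CSGALNACT1 changed by -1.43 ± 0.14, SNX29 by -1.36 ± 0.13 and the glutamate receptor gene GRIK2 by -1.32 ± 0.22, while the class I histocompatibility gene HLA-G rose by 0.81 ± 0.10 and HOPX by 0.81 ± 0.13. Between the polyamides the histone gene H3C8 was higher with polyamide 1 by 1.00 ± 0.19 and the GTPase gene GIMAP2 by 0.96 ± 0.17, and BBX, CPQ and the nuclear receptor gene NR4A1 were lower at -1.30 ± 0.21, -1.14 ± 0.16 and -1.03 ± 0.26. With DHT TMEM144 changed by -2.16 ± 0.12 and the adaptor gene DAB1 by -2.16 ± 0.16.

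The rise of AKR1C genes with polyamide 1 led to a hypothesis that other targets of NRF2, a transcription factor of the oxidative stress response, rose with them. The list for it left out the AKR1C genes, its prediction was written before the test, and its values under other scalings were added after the result was seen. Of 15 tested genes 6 were higher and 0 lower with polyamide 1: NQO1 at 0.80 ± 0.08, OSGIN1 at 0.63 ± 0.18, TXNRD1 at 0.56 ± 0.08, SQSTM1 at 0.42 ± 0.09, FTL at 0.37 ± 0.08 and GCLM at 0.36 ± 0.09. The median was 0.297 and camera with the preset correlation gave p = 0.000936, or p = 0.00638 with an estimated correlation. HMOX1, also an NRF2 target, was at 0.10 ± 0.18 and SLC7A11 at -0.10 ± 0.12, and neither was called. The list median was 0.135 with values as deposited and 0.181 with median-centred values, with camera p of 0.0162 and 0.015. Activation of NRF2 may therefore be part of the response to polyamide 1. With polyamide 2 the median was 0.0813, and camera gave p = 0.0081 upward with the preset correlation, or p = 0.0198 with an estimated correlation. The median was -0.119 with values as deposited and -0.0893 with median-centred values, with camera p of 0.448 and 0.451. The median of all genes was then -0.154 and -0.124. The sign of the list median and the call for polyamide 2 thus depended on the scaling. Between the polyamides the list was higher with polyamide 1 by a median of 0.161, and camera with the preset correlation gave p = 0.0132.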
